A study of Homo sapiens with 6 samples.

How the data were processed

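RNA was measured by 3' sequencing in HMC3, an immortalised line of human microglia, in 3 Control libraries and 3 libraries of cells given IL-33 for 24 h. Per the labels' protocols, RNA was extracted with TRIZOL and libraries were made with the Lexogen QuantSeq 3' FWD kit, which reads a short tag near the 3' end of polyadenylated transcripts, so that a gene's count does not grow with its length. The kit keeps the strand of the transcript. The authors deposited 1 table of whole-number read counts per gene symbol with a column for each of the 6 libraries. STAR 2.7.5a, HTSeq 0.6.1, edgeR and the build hg38 are named per the submitters' processing notes, with no version for edgeR and no role for any tool. The annotation, the strand setting of the counting and any filter on reads or genes are not given in the sources used here. A 3' tag that falls outside the annotated 3' end of a gene is not counted for it, and reads shared by near-identical genes can be lost or split in ways that the table does not show.

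The table had 27470 rows, of which 1 held no values and was left out. Of the other 27469 genes, 10205 had 0 counts in all 6 libraries. Each column's name matched the title of 1 library. Library totals ran from 5739947 to 10217529 counts, so that 3 counts, the limit below which a gene at 0 cannot be placed, corresponded to between 0.293 and 0.543 CPM (counts scaled to a library of 1e6). Intervals and limits based on counts cover counting error only, because reads made by PCR without molecular identifiers are not independent molecules.

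Genes were tested with edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr at its default count minimum of 10 and total minimum of 15, library sizes were scaled by TMM, and IL-33 was compared with Control by the quasi-likelihood test with robust estimation, group as the sole term and Benjamini-Hochberg adjustment at 0.05. The filter left 12125 genes, which held 99.9% of the counts. CPM values were computed from TMM-scaled library sizes, and log-scale levels with a prior count of 2. DESeq2 1.42.0 and limma-voom (limma 3.58.1) served as other tools. Gene lists were tested with camera at a preset correlation of 0.01 on the same 6 libraries, then with a correlation estimated for each list and with fry. A list was tested when 5 or more members passed the filter, which 29 of 34 lists did.

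The 34 lists held 880 distinct genes, of which 800 were found in the table as given, 60 under an older symbol and 20 not at all. The mitochondrially encoded transcripts, 15 genes, were among those not matched. Positions, strands and transcript types came from GENCODE release 29 on GRCh38, matched by symbol. Figures were drawn with matplotlib 3.10.9.

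The groups, the tests, the lists and the rule for naming genes were set before the data were examined. The rule named IL33 and the genes of its receptor first, then genes past the threshold at a mean of 10 CPM or more with groups that did not overlap. With fewer than 5 such genes in a direction, it named the 5 with the smallest unadjusted p in that direction at 10 CPM or more, as not passing. It also named up to 4 members with the smallest p from each called list and from the interferon-stimulated, NF-kB, cytokine and microglia lists. A gene that this rule named is not reported here. Other genes were named after their values were seen, to describe a group or a library.

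The procedure was tested on simulated counts drawn from the means, dispersions and totals of these libraries, in 5 runs with 200 changed genes each. It found 21.2% of genes changed 1.5-fold, 60.0% of those changed 2-fold and 85.5% of those changed 4-fold, and among genes of 10 CPM or more 32.0%, 82.2% and 98.3%. False calls made up 11.6% of the simulated calls, above the nominal share. A list of 25 genes shifted by 0.5 on the log2 scale was called in 5 of 5 runs with either correlation, and 0 of 45 unshifted lists were called with either one. The simulated genes varied independently of each other, so this gives no measure of how lists of correlated genes behave. For the same reason, no simulated library stood apart across many genes, as a Control library did here. The shares of changed genes found may therefore be higher than the procedure would reach in these data.

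The alternatives tried were DESeq2's size factors, library size alone, no low-count filter, a filter at 10 CPM, both other tools, the replicate number as a block, 2 other thresholds and each library left out in turn. After the data were examined, a correction for transcript GC content and fits by other tools without Control 3 were added. Replicates were compared before averaging. The chi-square per degree of freedom between libraries of a group lay between 5.61 and 16.5, so no pair held the same counts within sampling noise, as a library deposited more than once would, and none were merged. This does not show that the libraries come from separate cultures.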

Results

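The data describe HMC3, a human microglial line immortalised with the SV40 large T antigen, after 24 h with interleukin-33 (IL-33) and without it. IL-33 is a cytokine of the interleukin-1 family that binds the receptor ST2, encoded by IL1RL1, together with the accessory protein encoded by IL1RAP. The 3 Control libraries held 9933395, 8254108 and 5739947 counts, and the 3 IL-33 libraries 9544502, 10217529 and 8294747. Between 13864 and 14983 genes were detected per library, and the 10 most abundant genes took between 9.59% and 10.4% of the counts. Nothing in the labels says that the libraries come from separate cultures, so p-values measure the spread between these libraries, which may be technical.

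Pairs of libraries correlated with Pearson's r between 0.952 and 0.974 across the tested genes on a log CPM scale. Control 3, the library of lowest depth, stood apart from the others. The first principal component, with 35.4% of the variance, placed it at 55.0 and the other 5 libraries between -18.0 and 0.86. Its mean correlation with the others was 0.956, against 0.967 to 0.970 for the rest.

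The comparison of IL-33 with Control addressed which transcripts differ in HMC3 after 24 h of the cytokine. No single gene passed the test. Among genes at 10 CPM or more, the 5 with the smallest p were higher with IL-33 and included 2 abundant nuclear long noncoding RNAs, NEAT1, the scaffold of paraspeckles, and MALAT1, which localises to nuclear speckles. The counts are per gene symbol and do not show which transcript forms of these 2 genes were read. NEAT1 measured 152 ± 19.1 CPM in Control and 335 ± 115 CPM with IL-33 (SD, n = 3 each), and MALAT1 86.6 ± 22.9 and 142 ± 20.4 CPM. Interferon-stimulated genes had a median log2 fold change of 0.37, with a call by camera at a preset correlation that was lost (adjusted p = 0.892 with an estimated correlation) and that rested on IL-33 2. NF-kB targets and cytokine genes showed no shift that passed a test.

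IL33 had 0 counts in all 6 libraries, which allows up to 0.543 CPM in the library of lowest depth and 0.293 CPM in that of highest depth. IL1RL1, on chromosome 2 from 102311502 to 102352037 (GRCh38), had 3 counts in Control 3, 8 in IL-33 2 and 0 in the other 4 libraries. Its annotation overlaps IL18R1 on the same strand, which had 4 counts in all. The messenger of the IL-33 receptor was therefore at or near the detection limit in both groups, and no fold was computed. IL1RAP was measured at 6.23 ± 0.905 CPM in Control and 5.37 ± 2.45 CPM with IL-33, a log2 fold change of -0.23 ± 0.39 (SE). The signalling list that holds these genes (17 tested members, 6 of them above 0) had a median log2 fold change of -0.07 and an adjusted p of 0.767 by camera. Downstream of the receptor, the adaptor gene MYD88 lay at 2.91 CPM over the 6 libraries with a log2 fold change of 0.03 ± 0.57, and the kinase gene IRAK1 at 168 CPM with -0.07 ± 0.13.

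Of 12125 genes tested with edgeR's quasi-likelihood test, 0 changed at a Benjamini-Hochberg adjusted p of 0.05, 0 higher and 0 lower, and the smallest adjusted p was 0.643. At an unadjusted p under 0.05 there were 295 genes, 176 higher and 119 lower, where 606 would be expected at 5% of the genes tested. Without Control 3 there were 794 among 12611 genes tested. DESeq2 called 0 genes, with 355 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0828. With limma-voom 0 genes were called and 340 had an unadjusted p under 0.05. The 3 IL-33 values lay all above the 3 Control values in 551 genes and all below in 426, together 8.06% of the genes tested, where chance gives 10%. The biological coefficient of variation was 18.8%, and the 95% interval of the log2 fold change lay within -1 to 1 for 8895 genes (73.4%), and for 96.9% of the 8331 genes at 10 CPM or more.

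At 10 CPM or more, the 5 genes with the smallest p among those higher with IL-33 did not pass the test. KIRREL3-AS2, an antisense RNA on chromosome 11 from 126940746 to 126945090, measured 8.38 ± 0.544 CPM in Control and 23.6 ± 10.2 CPM with IL-33, a log2 fold change of 1.48 ± 0.29 (SE) with an adjusted p of 0.643 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It overlaps KIRREL3 on the opposite strand, with 1192 counts in all, and without a stated strand setting reads of this pair cannot be told apart. NEAT1 (chromosome 11, 65422774 to 65445540) had a log2 fold change of 1.14 ± 0.25 and MALAT1 (chromosome 11, 65497688 to 65506516) of 0.70 ± 0.17. PCGF3, a Polycomb group ring finger gene, went from 22.6 ± 4.40 to 37.8 ± 5.23 CPM (log2 fold change 0.73 ± 0.19). TNRC6C, of the GW182 family of microRNA silencing factors, went from 13.5 ± 1.41 to 23.1 ± 3.31 CPM (0.77 ± 0.22). In each of these 5 genes the IL-33 libraries all lay above the Control libraries.

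At 10 CPM or more, the 5 genes with the smallest p among those lower with IL-33 did not pass either, and their IL-33 values all lay below the Control values. SHROOM3, an actin-binding regulator of cell shape, measured 14.9 ± 1.16 CPM in Control and 8.22 ± 1.13 CPM with IL-33, a log2 fold change of -0.86 ± 0.26. TENM3, a teneurin adhesion receptor, had -0.82 ± 0.26 and SYTL2, a synaptotagmin-like Rab effector, -0.78 ± 0.27. The better measured CDC42EP1, an effector of the GTPase CDC42, had -0.42 ± 0.14, and KCTD20, at 374 ± 19.0 CPM in Control and 308 ± 12.95 CPM with IL-33, had -0.28 ± 0.09. All 5 had an adjusted p of 0.999 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

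**Figure D1:**
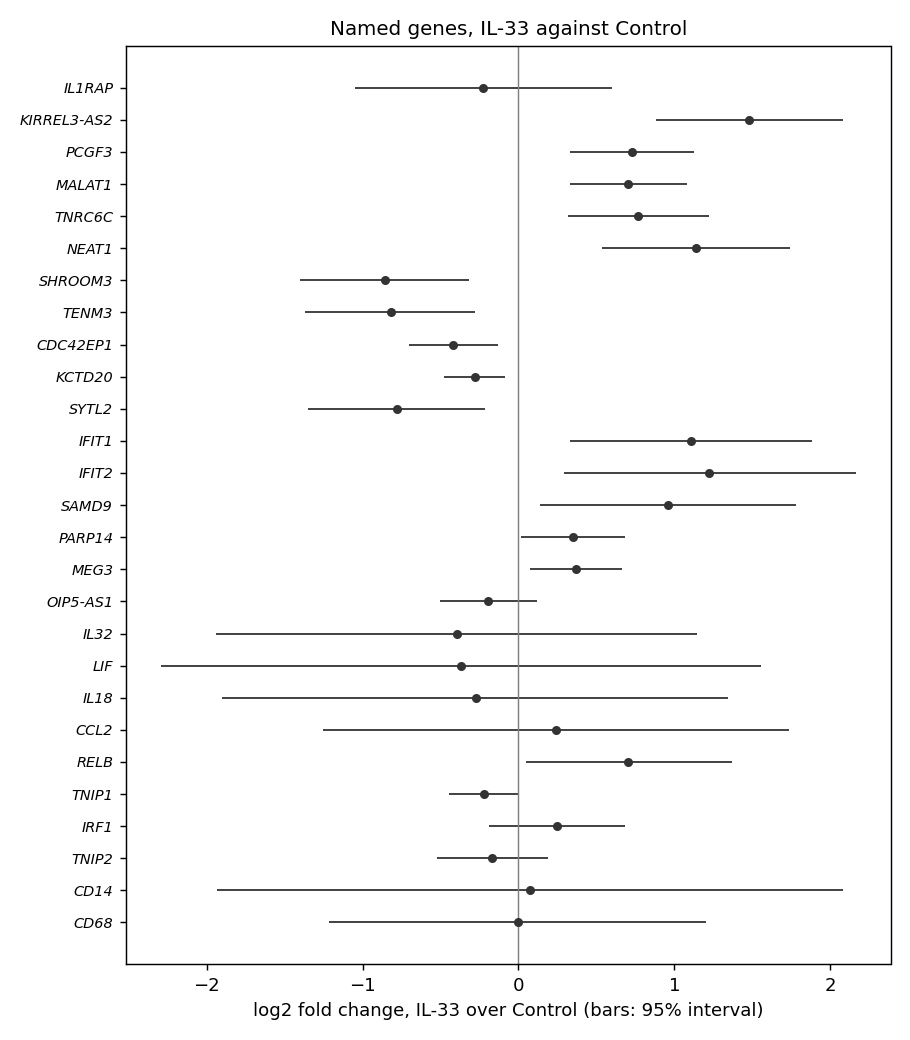
Log2 fold change of IL-33 over Control (x axis) for tested genes named by rule and reported here (y axis), with points for the estimate and bars for its 95% interval from edgeR, 3 libraries per group. KIRREL3-AS2 stands highest at 1.48 and SHROOM3 lowest at -0.86, and the bars of the low-count cytokine genes IL32, LIF, IL18 and CCL2 are the widest together with that of CD14.

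The call of 0 genes depended on 2 settings. Without the low-count filter edgeR called 3 genes, all higher (KIRREL3-AS2, MALAT1 and NEAT1). Their folds hardly moved, while the degrees of freedom of the test rose, for KIRREL3-AS2 from 18.9 to 59210. The estimate of the spread, not the fold, made these calls. Without Control 3 edgeR called 6, namely KIRREL3-AS2, LTB4R and MALAT1 higher and PAIP2, ADAMTSL1 and ARCN1 lower. Of the 6, DESeq2 called 0 and limma-voom 5, all but KIRREL3-AS2. In LTB4R, PAIP2 and ADAMTSL1, Control 3 (21.5, 109 and 5.79 CPM) lay within the range of the IL-33 libraries. In ARCN1 it lay below them (72.2 CPM), with Controls 1 and 2 above (124 and 128 CPM). The calls of LTB4R, PAIP2, ADAMTSL1 and ARCN1 therefore rest on leaving out a Control library that went against them. In KIRREL3-AS2 and MALAT1 Control 3 lay below the IL-33 libraries, as Controls 1 and 2 did. The log2 fold change of MALAT1 was 0.51 without Control 3, against 0.70 with all libraries. With a library left out, that of KIRREL3-AS2 ran from 1.10 to 1.74 and that of NEAT1 from 0.82 to 1.31.

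Interferon-stimulated genes formed 1 of the 2 lists called among 29 tested. Of 32 tested members, 29 had a log2 fold change above 0, 4 of them at an unadjusted p under 0.05, and the adjusted p was 4.4e-07 by camera with a preset correlation. The call was lost when the correlation between members was estimated (adjusted p = 0.892 with an estimated correlation), and fry gave an adjusted p of 0.908. The 4 members with the smallest p were IFIT1 (10.1 ± 3.10 CPM in Control, 21.7 ± 12.1 CPM with IL-33, log2 fold change 1.11 ± 0.36), IFIT2 (1.22 ± 0.45), both interferon-induced RNA-binding proteins, the antiviral factor SAMD9 (0.96 ± 0.38) and the ADP-ribosyltransferase PARP14 (0.35 ± 0.16). Without IL-33 2, IFIT1 had 0.55 and SAMD9 0.33. In none of these 4 did the groups separate, 0 members of the list changed over all genes or adjusted over the list alone (smallest 0.205), and IFIT1 and IFIT2 both overlap LIPA on the opposite strand (636 counts in all) and belong to a family of similar genes. The more abundant ISG15, at 80.5 CPM over the 6 libraries, had 0.31 ± 0.15. The list's mean level per library, in log2 units around each gene's mean, was -0.18, 0.01 and -0.39 in Control and 0.20, 0.74 and -0.38 with IL-33. The difference of 0.37 was smaller than the range of 1.12 within the IL-33 group (two-sided exact permutation p = 0.4, where 3 against 3 allows no less than 0.1). Without IL-33 2 the median was 0.16 and the call was lost, with an adjusted p of 0.343 by camera, and without IL-33 3 the median was 0.62 with an adjusted p of 1.6e-21 by camera. In Control 3 the list's median lay at -0.10 log2 units from the mean of the other Control libraries.

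Nuclear-retained RNAs were the other called list. Of 13 tested members, 12 had a log2 fold change above 0, with a median of 0.08, a mean of 0.21 and an adjusted p of 0.0012 by camera with a preset correlation. The adjusted p = 0.892 with an estimated correlation, and fry gave 0.908. Over all genes 0 members changed, with an adjusted p of 0.999 for MALAT1 and NEAT1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 2 did by the same test, MALAT1 with 0.0177 and NEAT1 with 0.0223. That adjustment leaves out the other lists tested, and the list itself was called on the same libraries. The values over the list alone are therefore no separate evidence that these 2 genes changed. MEG3, an imprinted long noncoding RNA, had a log2 fold change of 0.37 ± 0.14 (0.16 without IL-33 3), and OIP5-AS1, which overlaps OIP5 on the opposite strand (1743 counts in all), had -0.19 ± 0.15 (-0.35 to -0.09 with a library left out). TUG1, at 169 CPM, had 0.00 ± 0.12, KCNQ1OT1 0.08 ± 0.17 and NORAD 0.10 ± 0.14. NORAD is mostly cytoplasmic, and the list also holds host genes of small nucleolar RNAs (SNHG1, SNHG5, SNHG8, SNHG12, GAS5 and ZFAS1) that are not confined to the nucleus. In Control 3 the list's median lay at -0.17 log2 units from the other Control libraries, and without that library the call was lost (median 0.04, adjusted p of 0.348 by camera), while without Control 2 the median was 0.15 and the list was called.

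**Figure D2:**
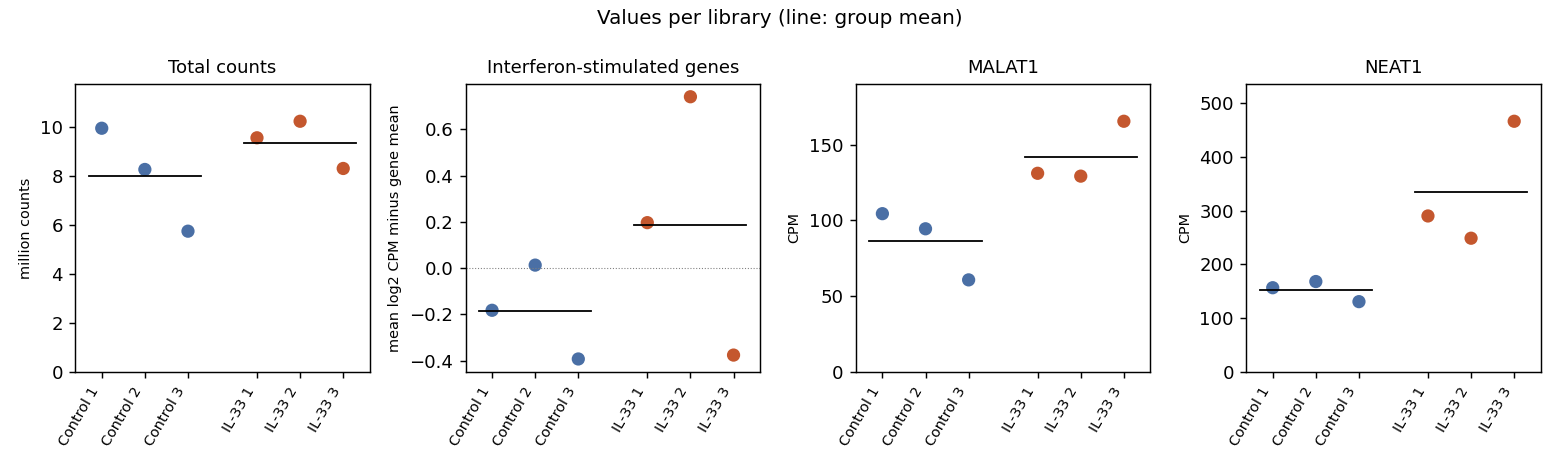
Values of each library (x axis, Control in blue and IL-33 in orange, line at the group mean): total counts (in units of 1e6), the mean level of the interferon-stimulated list in log2 units around each gene's mean, and MALAT1 and NEAT1 in CPM. The interferon list spans -0.38 to 0.74 within the IL-33 group, while the IL-33 values of MALAT1 and NEAT1 all lie above their Control values.

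NF-kB targets and feedback genes, which interleukin-1 family receptors act on through MyD88, did not pass. Of 25 tested members 15 had a log2 fold change above 0, the median was 0.05 and the adjusted p 0.785 by camera, and 0 members changed, also when adjusted over the list alone (smallest 0.703). RELB, an NF-kB subunit, had a log2 fold change of 0.71 ± 0.32 at 7.96 CPM, with all IL-33 values above the Control values. TNIP1, an inhibitor of NF-kB, had -0.22 ± 0.11 at 125 CPM, with all IL-33 values below the Control values. The related TNIP2 had -0.17 ± 0.17 (-0.27 to -0.09 with a library left out) and the transcription factor IRF1 0.25 ± 0.21 (0.10 to 0.36). NFKBIA, an early target that encodes an inhibitor of NF-kB, had -0.06 ± 0.13 with a 95% interval from -0.34 to 0.22. The intervals of 17 of the 25 members lay within -1 to 1.

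Inflammatory cytokines and chemokines were barely measured. Of 28 listed genes, 7 had 0 counts in all libraries, 13 had at most 3 in every library, and 6 could be tested. CXCL10 had 0 counts, TNF 1 count, CXCL8 8 counts over both groups (5 and 3) and IL6 11 (8 and 3). IL11, the sole member at 10 CPM or more, measured 81.6 ± 9.18 CPM in Control and 81.2 ± 6.42 CPM with IL-33, and the 95% interval of its log2 fold change ran from -0.28 to 0.25. The low-count members IL32, LIF, IL18 and CCL2 had log2 fold changes of -0.39 ± 0.74, -0.37 ± 0.87, -0.28 ± 0.77 and 0.24 ± 0.72, and their direction differed between settings. The list's median was -0.14 although camera placed it as higher, with an adjusted p of 0.921, and 0 members changed over all genes or adjusted over the list alone (smallest 0.976). In Control 3 the list's median lay at -2.80 log2 units from the other Control libraries. Members with at most 3 counts in every library lay at the detection limit, so a fall in them could not be seen. Which rises could be seen was not tested.

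Most microglia and macrophage markers were likewise near the detection limit, with 14 of 28 at 0 counts in all libraries, 20 at no more than 3 in every library, and 3 that could be tested, too few for a test of the list. ITGAM, P2RY12, TMEM119, CX3CR1, SPI1 and TYROBP had 0 counts. Among the tested members, the lipopolysaccharide co-receptor CD14 had a log2 fold change of 0.07 ± 0.96 and the lysosomal glycoprotein CD68 0.00 ± 0.58. Adjusted over the list alone, 0 of the 3 tested members changed.

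Of the 29 tested lists, 27 were not called, and the smallest adjusted p among these was 0.430 by camera, for NRF2 targets (23 members, median log2 fold change -0.06) and for immediate early and MAPK feedback genes (25 members, median -0.04). EGR1, an immediate early transcription factor, had -0.34 ± 0.14. Cell cycle genes were measured closely: the median was -0.02 for 29 genes of S phase, with all 29 intervals within -1 to 1, and -0.06 for 30 genes of mitosis, with 29 of 30. The intervals of 37 of 39 nuclear-encoded genes of oxidative phosphorylation and of 72 of 73 cytosolic ribosomal proteins lay in the same bounds. Cholesterol biosynthesis had a median of -0.02 over 24 genes (adjusted p 0.851), lysosome and autophagy genes -0.02 over 29 (0.921), antigen presentation 0.02 over 19 (0.851), p53 targets 0.08 over 27 (0.607) and genes of phagocytosis and amyloid clearance -0.03 over 15 (0.692), all by camera. In each list of this paragraph 0 members changed, over all genes or adjusted over the list alone.

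**Figure D3:**
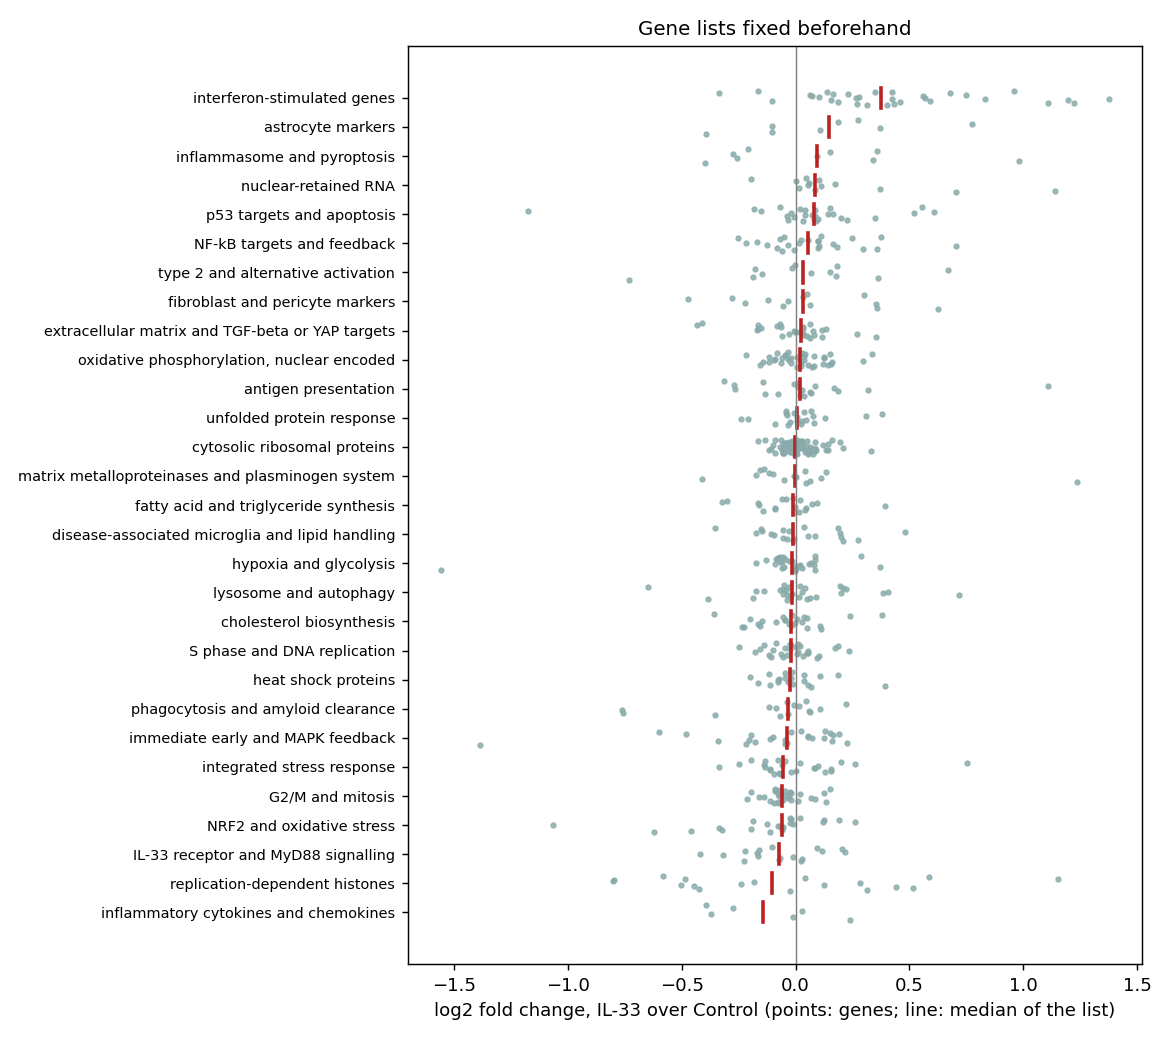
Log2 fold changes of IL-33 over Control (x axis) of the tested members of 29 gene lists (y axis), with points for genes and a line for each list's median. Interferon-stimulated genes have the highest median, 0.37, and inflammatory cytokines and chemokines the lowest, -0.14.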

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

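The GC corrections and the fits by other tools without Control 3 were chosen after the results were seen. The count of 0 changed genes was the same with DESeq2's size factors, library size alone, a 10 CPM filter, DESeq2, limma-voom, a fold of 2 or more, an adjusted p under 0.1 and a GC correction. Without the low-count filter, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3 genes, 3 higher, with adjusted p of 9.1e-07 for NEAT1 and 5.7e-05 for KIRREL3-AS2 and MALAT1. The log2 fold change of NEAT1 was 1.14 in both fits, while its degrees of freedom went from 6.30 to 48.3 and its SE from 0.25 to 0.14, so the estimate of the spread, not the fold, made the call. With a library left out the counts ran from 0 to 15 changed genes, 0 to 3 higher and 0 to 13 lower. With edgeR, the sole tool run for each library, 0 changed without any of the other 5 libraries. Without Control 3, edgeR called 6 (3 higher, 3 lower), as with DESeq2's size factors, limma-voom 15 (2 higher, 13 lower), with 5 of edgeR's 6 among them, and DESeq2 0, with 794 genes at an unadjusted p under 0.05 against 295 and the biological coefficient of variation at 15.3% against 18.8%. The called lists, 2 in number, came to 0 with an estimated correlation and 0 by fry, and to 1 to 2 with a library left out, the nuclear-retained list being lost without Control 3 and the interferon list without IL-33 2 (medians 0.04 to 0.15 and 0.16 to 0.62 over the libraries left out). The labels do not say whether the replicate numbers pair the libraries. Correlations of same-numbered deviations were -0.086, 0.027 and -0.136, each under the highest with another number. Deviations from the mean of so few libraries constrain each other, so this cannot exclude a pairing. With the replicate block 0 genes changed (0 with a GC correction as well) and 2 lists were called. Of 270 values of 27 named genes, 253 kept direction and side of the threshold, 2 passed it (KIRREL3-AS2 and MALAT1 without Control 3) and 15 were reversed, all in genes with intervals across 0. LIF was at 0.11 with the block. With a library left out, the log2 fold change ran from -0.63 to 0.038 for IL1RAP, -1.39 to 0.42 for IL32, -0.91 to 0.73 for LIF, -1.17 to 0.19 for IL18, -0.24 to 0.69 for CCL2, -0.58 to 1.42 for CD14 and -0.67 to 0.25 for CD68. Beyond what is said of the 3 genes called without the filter, the cause was not tested. In the cytokine and microglia lists 13 of 28 and 20 of 28 genes had at most 3 counts in every library, and whether depth or lack of expression sets this was not tested.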

Other observations

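The tests of scaling and of variation between libraries for the interferon-stimulated genes and that of the other nuclear-retained RNAs were chosen only after the result was seen. Some genes usual in mesenchymal cells were abundant, named after their values were seen. VIM measured 1553 CPM over the 6 libraries, TAGLN 1484, COL1A1 721 and THY1 210, and FN1 reached 3672 CPM, while 20 of 28 microglia markers had at most 3 counts in every library. The log2 fold changes of the 5 abundant genes between IL-33 and Control ran from -0.06 ± 0.11 for THY1 to 0.06 ± 0.12 for COL1A1. Markers of other brain and immune cells were few: 3 of 16 neuron markers, 3 of 12 oligodendrocyte markers and 3 of 16 lymphocyte and mast cell markers passed the low-count filter, too few for a test of these lists. The astrocyte list (8 tested members, median log2 fold change 0.15, adjusted p of 0.785 by camera) and the fibroblast and pericyte list (13 members, median 0.03, adjusted p 0.851) were tested and not called. As a whole the fibroblast and pericyte list was not abundant, with a median of 4.18 CPM, 4 of 20 members at 0 counts in all libraries and 8 at 10 CPM or more. GFAP had 10 counts in all, 5 per group.

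Control 3 differed from the other Control libraries in named groups, given here as values of 1 library with genes chosen after their values were seen. Cytokine genes lay at a median of -2.80 log2 units, with 5 of 6 members lower, and inflammasome genes at -0.72, with 7 of 9 lower. LIF had 0 counts in Control 3, against 34 and 67 in Controls 1 and 2, IL18 2 against 36 and 36, and CCL2 1 against 24 and 24. PLAU, the urokinase gene, measured 1.81 CPM there against 18.4 and 16.95, and MYC 10.1 against 41.3 and 30.4. Replication-dependent histones lay at 0.48 and genes of phagocytosis and amyloid clearance at 0.29, while IL32 went the other way from the other cytokines, at 4.70 CPM against 1.49 and 1.20.

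The position of Control 3 apart from the other 5 libraries was set against depth, GC content and transcript length. Thinning all libraries to its total left the gap of its mean correlation to the next lowest library at 0.0102, from 0.0110, which argues against depth. The correlation across genes of its deviation with transcript length was -0.032. A 3' tag count does not grow with transcript length, so a small value could arise whatever set this library apart and decides nothing. With transcript GC content the correlation across genes was 0.272, the largest of the 6 libraries in size (the next was -0.181, in Control 2, whose deviation is measured partly against Control 3), so a GC bias may contribute. Removing each library's trend with this GC content left the gap at 0.00998, from 0.0109, so that trend does not account for the whole. The GC content was that of whole annotated transcripts, while the reads are short 3' tags. A bias with the GC content of the tags themselves was not tested. A different state of the cells behind that library or an unrecorded difference in handling stays open and was not tested.

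Interferon-stimulated genes were higher in IL-33 libraries 1 and 2 and not in 3. The list's median log2 fold change lay 0.38 above that of the other 12093 tested genes (95% bootstrap interval over genes 0.24 to 0.52). A scaling factor moves all genes alike, so scaling alone would not give such a gap. But camera had already called the list against the other genes, so a positive gap was fixed before this test. The interval also takes the members as independent, although their estimated correlation was 0.39, so it is too narrow. Depth stays open: thinning all libraries to 1 depth gave a median of 0.34 against 0.37, but random thinning keeps the expected ratio of genes counted this well and decides nothing. The range of the list's level within the IL-33 group, 1.12, was larger than the difference between groups, 0.37 (exact permutation p = 0.4, where the design allows no less than 0.1, so that p alone decides nothing). The list was called in 5 of the 10 splits of the 6 libraries into 3 and 3, the real one included. Of the called splits, all but that of Control 1, IL-33 1 and IL-33 3 against the rest kept IL-33 1 and 2 together. An effect in those 2 libraries would give such calls too, so the splits decide nothing. Variation between libraries that does not follow the treatment stays open, since the range within the IL-33 group was larger than the difference between groups. An effect of IL-33 remains an open, untested alternative.

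MALAT1 and NEAT1 were higher in all 3 IL-33 libraries. Thinning left their mean log2 fold change at 0.92, from 0.92, which it would do whatever the cause, so it does not bear on depth. Controls 1 and 2, at 9933395 and 8254108 counts, had NEAT1 at 157 and 168 CPM and MALAT1 at 104 and 94.5 CPM. IL-33 libraries 1 and 3, of similar depth at 9544502 and 8294747 counts, had NEAT1 at 290 and 466 CPM and MALAT1 at 131 and 165 CPM. For these 2 genes, such values argue against depth. A larger share of nuclear RNA stays open. The other 11 members of the nuclear-retained list had a median of 0.061 (-0.074 and 0.195 at the median minus and plus 1 SD), but most of these are not confined to the nucleus. In median log2 fold change, 304 lincRNA and antisense genes lay 0.070 above 11157 protein-coding genes (95% bootstrap interval 0.039 to 0.115). Part of the difference could therefore be shared by noncoding RNA. Regulation of these 2 RNAs by IL-33 is an untested hypothesis that the test over all genes does not carry.

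The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For the count of changed genes the real value was 0, which all 10 splits reach by construction, and the highest other count was 45. For gene lists, 3 of the 10 splits, the real one included, gave at least the real 2, and the highest other was 5. The split with 45 genes and 5 lists set Controls 1 and 2 and IL-33 3 against the rest, with 1230 genes at an unadjusted p under 0.05 against 295 in the real one. It was picked as the highest of the splits. Whether it reflects a structure of the samples other than the treatment was not tested.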
